A study of Homo sapiens with 4 samples.

How the data were processed

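RNA polymerase II ChIA-PET, which ligates DNA ends held together in cross-linked chromatin after immunoprecipitation of the polymerase and sequences them as paired-end tags (PETs), was analysed in 4 prostate cell lines. These were the metastatic prostate cancer lines VCaP, LNCaP and DU145 and the epithelial line RWPE-1, which comes from prostate tissue of normal histology. Per the labels, cells were fixed with EGS and formaldehyde, chromatin was sheared, and the ligated products were turned into Nextera libraries after proximity ligation through a bridge linker. Each line had 1 library. No replicates were used here, so no spread between replicates could be measured, no test was made between lines, and every interval covers counting error only. PETs carry no molecular identifier, and whether copies of a ligation product were removed by the positions of their ends is not given in the sources used here. A count of PETs may therefore include repeated copies of 1 product.

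For each line the authors deposited a list of pairs of anchors on the same chromosome, with a peak name for each anchor. The value of each pair was taken as counts of PETs joining the anchors, as deposited, without normalization; the values were whole numbers from 1 upward with no filter on PETs and no column of false discovery rates. A further whole number per anchor, which was constant for each peak, was read as the deposited counts of tags at that anchor; this reading rests on the layout of the lists. The genome build, per the submitters' processing notes, was hg19, and mitochondrial pairs in the lists reached position 16571. The aligner, peak caller and interaction caller are not given in the sources used here. Coordinates are those of the lists, written 1-based, and cytogenetic bands were taken from the hg19 band table of circlize 0.4.16. The lists pair no anchor with a gene, and no gene annotation on hg19 was used here, so anchors are given by position and band and no gene is named from a position. The planned promoter classes, PETs per promoter and 11 gene lists were therefore not analysed here.

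A called interaction was a deposited pair with at least 3 PETs. Distance was measured between anchor midpoints. Counts carry exact Poisson 95% intervals and shares exact Clopper-Pearson 95% intervals. An interaction was shared when both of its anchors overlapped, by at least 1 bp, both anchors of 1 called interaction in the other line. Each share was set beside the mean over 100 circular shifts of the interactions within their chromosomes. For pairing between common anchors, called interactions of 10 kb to 1 Mb whose anchors both overlapped deposited anchors of the other line were compared with pairs of common anchors at the same distance, within 20%, that carried no PET in the first line; these pairs were matched on distance and not on anchor depth.

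Called anchors of the 4 lines were merged where they overlapped into 13609 regions. The rate of a region was the number of PETs of its called interactions per 100000 called PETs of the line. Ratios between lines took a line with fewer than 3 PETs as having 3 PETs, applied per line. A ratio to a line without called PETs is therefore a lower bound for the observed called PETs, written as at least. It does not cover counting error, and pairs with 1 or 2 PETs do not enter it. With every deposited pair some of these ratios were lower. Ratios to a line with called PETs carry exact conditional binomial 95% intervals. Regions were named by a rule fixed before the data were examined, written for genes with regions as its stated substitute: the 6 regions per line with the highest ratio over the highest other line among those with at least 20 PETs, the 6 regions with the highest minimum rate over the 4 lines, and the 3 regions per line with most distinct partners. A partner is an anchor joined to the region, so contacts between anchors merged into 1 region are counted; they carried 2.57% of called PETs in RWPE-1 to 4.61% in VCaP. Networks were connected sets of called anchors. Long-range interactions were those over 1 Mb, counted also by pairs of 1 Mb bins. Anchor depth per line was scaled to the line's total anchor depth.

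Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, networkx 3.6.1 and matplotlib 3.10.9, with random seed 7. Parts of the analysis were tested on simulated data. With a DU145 list of 2699 interactions whose copies were partly moved, true shared shares of 19.5% and 59.4% were returned as 19.5% and 59.4%. These came from a direct comparison of all pairs, and kept copies moved by less than an anchor width, so the outcome was given by construction. The faster search used for the results was checked against direct comparison for DU145 interactions in VCaP, and both gave 16.1%. With 200 of the 13609 regions raised in VCaP against the other 3 lines, the rule for line-specific regions returned 189 of them, and it returned 0 of the unchanged regions. The simulation holds for VCaP against the other lines only. Its counts had Poisson error without spread between libraries or repeated PETs, so it gives no rate of false line-specific regions in these data.

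Depth differed between lines. The deposited lists held 88374 PETs for VCaP, 49743 for LNCaP, 38130 for DU145 and 46666 for RWPE-1. Alternatives fixed in advance were every deposited pair, a minimum of 5 PETs, PETs drawn at random down to the smallest library, overlap of at least 50% of the shorter anchor or anchors within 5 kb as shared, a median-of-ratios scale, the number of interactions in place of PETs, interactions of 10 kb to 1 Mb only, and long-range limits of 500 kb and 2 Mb. Added after seeing the data were the removal of mitochondrial pairs, an equal number of pairs per line, the distance window for the sharing and presence counts, the presence count without DU145, and the removal of contacts inside a region. Alternatives on false discovery rates, promoter windows and the pseudocount of the gene lists were not run, since they need values not used here.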

Results

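RNA polymerase II-associated chromatin interactions were mapped by ChIA-PET in 4 prostate cell lines, with 1 library per line. VCaP and LNCaP are cancer lines that express the androgen receptor, derived from a vertebral and a lymph node metastasis. DU145 is a cancer line from a brain metastasis that lacks androgen receptor activity. RWPE-1 is an immortalised, non-tumorigenic prostate epithelial line. The comparisons asked how far the interactions were common to the 4 lines, which regions were particular to 1 line, and what separated the 3 cancer lines from RWPE-1. The deposited lists held 66187 anchor pairs for VCaP, 39071 for LNCaP, 24578 for DU145 and 28465 for RWPE-1. Pairs supported by a single PET made up 84.8% of the list in VCaP, 85.9% in LNCaP, 73.8% in DU145 and 67.3% in RWPE-1. The 4 lines have no replicates, so differences between them are described and not tested. Positions are given on hg19.

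Most called interactions in all 4 lines joined anchors less than 100 kb apart, and the lines differed in the shares of the shortest and the longest interactions. VCaP had 3846 called interactions (95% interval 3725 to 3970), LNCaP 1937 (1852 to 2025), DU145 2704 (2603 to 2808) and RWPE-1 3779 (3659 to 3901). The median distance was 23.1 kb in VCaP, 11.1 kb in LNCaP, 42.6 kb in DU145 and 28.2 kb in RWPE-1. Interactions under 10 kb made up 48.0% of LNCaP calls (45.8 to 50.3) and 28.2% of DU145 calls (26.5 to 30.0), and those over 1 Mb 0.671% of LNCaP calls and 17.2% of DU145 calls. The order of the lines by number of calls depended on depth. With PETs drawn down to the 38130 of DU145, VCaP had 1128 called interactions and LNCaP 1279, both fewer than the 2704 of DU145. Drawing down levels the total of PETs and not the PETs per pair. Pairs with a single PET made up 73.8% of the DU145 list against 84.8% in VCaP and 85.9% in LNCaP. Repeated counting was not separated from this order.

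**Figure D1:**
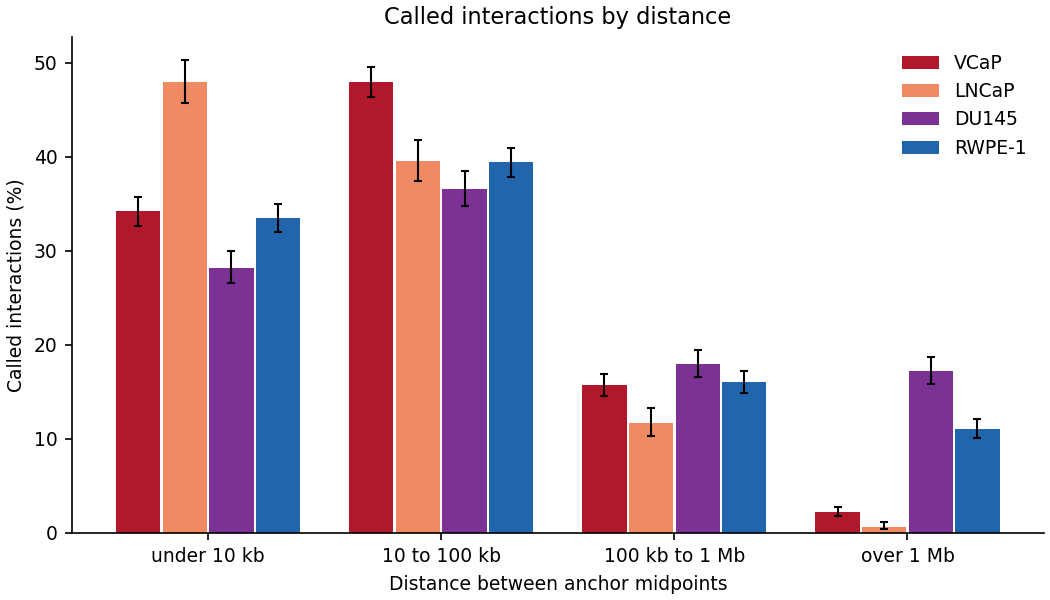
Share of called interactions (%, vertical axis) in 4 classes of distance between anchor midpoints (horizontal axis) for each line; error bars are exact binomial 95% intervals. Interactions over 1 Mb made up 17.2% in DU145 and 11.1% in RWPE-1 against 2.18% in VCaP and 0.671% in LNCaP.

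In each of the 4 lines most called interactions were not called in another line, and the closest pair was LNCaP and VCaP. Of the LNCaP interactions, 31.0% were also called in VCaP (29.0 to 33.1), against 14.4% in DU145 (12.8 to 16.0) and 13.8% in RWPE-1 (12.3 to 15.5). VCaP and RWPE-1 had lists of similar length. An interaction was also called in at least 1 other line for 38.5% of LNCaP calls (36.3 to 40.7), 27.0% of VCaP calls (25.6 to 28.4), 25.9% of DU145 calls (24.3 to 27.6) and 18.6% of RWPE-1 calls (17.4 to 19.9). Shifted copies of the same lists gave means of at most 0.296%. The shifts take anchors off the peaks of the other lines, so they give no chance level for pairing between common anchors. Among 10400 joined region pairs, 108 were called in all 4 lines. A pair with fewer PETs than the minimum in a line counted as not called there. Without replicates, the sharing between libraries of the same line is unknown, so these shares cannot show that the lines hold separate sets. With an equal number of pairs per line, 24.1% of LNCaP interactions were called in VCaP, 12.2% in DU145 and 10.2% in RWPE-1. With PETs drawn down to the smallest library, the share of LNCaP interactions called in VCaP was 17.9%, close to the 16.7% in DU145.

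**Figure D2:**
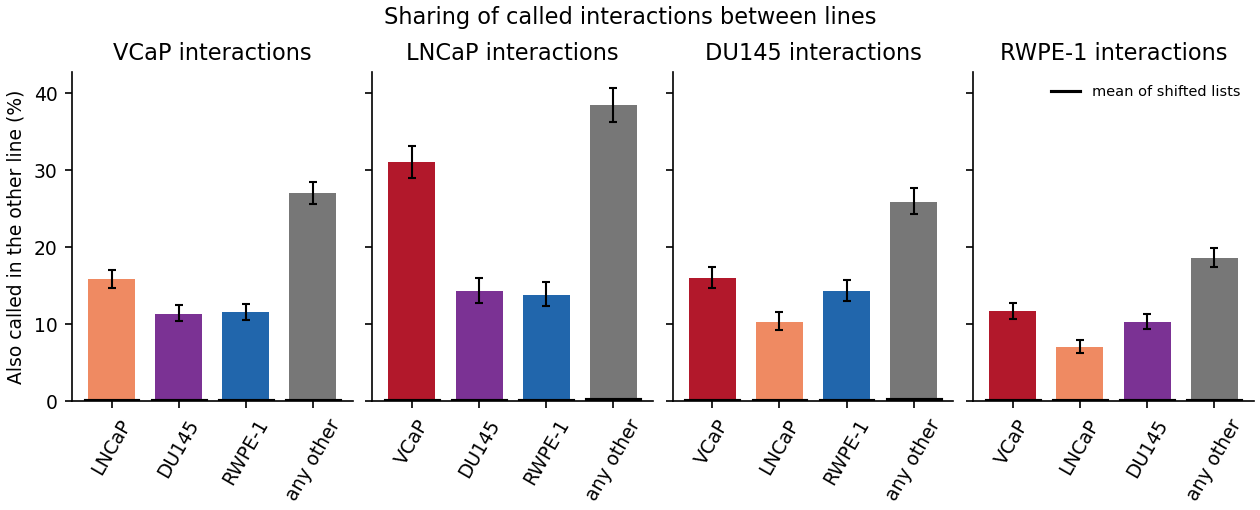
Share of the called interactions of each line (%, vertical axis) that were also called in each other line or in any other line (horizontal axis); error bars are exact binomial 95% intervals and black lines the mean of 100 shifted lists. The highest share between 2 lines is that of LNCaP interactions in VCaP, at 31.0%.

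Sharing of anchors was measured apart from that of interactions, which by definition need both anchors shared. An anchor of called interactions overlapped one of another line for 36.9% of RWPE-1 anchors (35.7 to 38.1), 47.0% of VCaP anchors (45.7 to 48.4), 51.1% of DU145 anchors (49.6 to 52.6) and 55.5% of LNCaP anchors (53.8 to 57.3). Between LNCaP and VCaP it was 43.6% of LNCaP anchors (41.8 to 45.3) and 25.2% of VCaP anchors (24.1 to 26.4). Overlap with any deposited anchor, pairs under 3 PETs included, was higher. Of the LNCaP anchors in called interactions, 78.6% overlapped a deposited anchor of VCaP (77.1 to 80.0), against 56.1% for DU145 and 56.1% for RWPE-1. In the other direction 77.7% of VCaP anchors overlapped a deposited anchor of LNCaP (76.5 to 78.8). RWPE-1 anchors were found least often elsewhere, with 70.3% (69.1 to 71.4) overlapping a deposited anchor of any other line, against 83.0% to 86.1% for the cancer lines. Deposited RWPE-1 anchors were also narrower, with a median of 1494 bp against 1725 to 1796 bp. Their median depth was lower, at 259 against 359 to 421. Whether these differences between the peak sets lower the overlap was not tested. Where both anchors of a called interaction of 10 kb to 1 Mb were present in the other line, they were joined there by at least 1 PET in 46.8% of cases (DU145 interactions in RWPE-1) to 74.8% (LNCaP interactions in VCaP). The same share was 11.3% to 24.3% for pairs of common anchors at matched distances without a PET in the first line.

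The regions with the highest minimum rates over the 4 lines lay in the mitochondrial genome and at 11q13.1, 15q22.31 and 6p22.2. Whether the mitochondrial PETs reflect binding of the polymerase was not tested. Of the 13609 regions, 399 (2.93%) had called interactions in all 4 lines. The 2 mitochondrial regions, at positions 9231 to 16571 and 1 to 4486, had the highest minimum rates, and mitochondrial pairs took 2.16% of called PETs in RWPE-1 to 5.33% in LNCaP. At 11q13.1 the region 65188319 to 65198903 of chromosome 11 had 634 PETs in VCaP, 55 in LNCaP, 80 in DU145 and 72 in RWPE-1. Its rate was 3200 PETs per 100000 in VCaP against 438 to 639 in the other lines. Part of these PETs, 314 in VCaP, 25 in DU145 and 49 in RWPE-1, joined anchors that both lay inside this merged region. Without them the rate was 1615 in VCaP, 609 in LNCaP, 440 in DU145 and 140 in RWPE-1. The lowest of these was below the lowest rates of the 15q22.31 regions (266 and 257) and of the 6p22.2 region (255). At 15q22.31 the regions 65587410 to 65590297 and 65596059 to 65598963 of chromosome 15 were joined to each other over 8.59 to 8.80 kb by 51 PETs in VCaP, 24 in LNCaP, 39 in DU145 and 46 in RWPE-1. The 6p22.2 region, 26122290 to 26127141 on chromosome 6, had 69 PETs in VCaP, 31 in LNCaP, 38 in DU145 and 42 in RWPE-1. Its leading partner in each line, about 33 kb away, carried 35 PETs in VCaP, 24 in LNCaP, 25 in DU145 and 25 in RWPE-1.

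The VCaP regions with the highest ratios over the other lines were on 6p and 13q34. Of 268 regions with at least 20 PETs in VCaP, 111 had a rate at least 2-fold above the highest other line. This number depended on depth: with PETs drawn down to the smallest library it was 25 in VCaP, 14 in LNCaP, 31 in DU145 and 16 in RWPE-1. The 6p22.3 region, 19836679 to 19840036 on chromosome 6, had 140 PETs with 19 partners. The other lines had no deposited anchor there, and so no called or deposited PET. Its rate was at least 21.3-fold higher than theirs. This ratio rested on contacts over 1 Mb: with interactions of 10 kb to 1 Mb only, the log2 ratio fell from 4.41 to 0.38 (-0.68 to 1.26). The leading partner, at 6p24.2 (11231557 to 11233778), lay 8606 kb away and had 60 PETs and a rate at least 9.12-fold higher; 33 of the 60 were the PETs that joined it to the 6p22.3 region. RWPE-1 had 3 called PETs at the 6p24.2 region, and the deposited PETs there were 2 in LNCaP, 4 in DU145 and 6 in RWPE-1. At 13q34, region 110436512 to 110440079 of chromosome 13 had 87 PETs and 18 partners with a rate at least 13.2-fold higher; the other lines had no called PET there and 5 to 9 deposited PETs. Region 111364170 to 111368939 of the same band had 213 PETs and 25 partners in VCaP against 10 PETs in LNCaP, 17 in DU145 and 10 in RWPE-1, which was 7.91-fold above DU145 (4.83 to 13.8). Further VCaP regions were at 19q13.41 (52400238 to 52410138, 58 PETs, at least 8.82-fold, with 1 deposited PET in LNCaP) and 11q13.1 (65183411 to 65184654, 55 PETs, at least 8.36-fold). The log2 ratio of the 11q13.1 region fell from 3.06 to 1.06 (0.25 to 1.76) with interactions of 10 kb to 1 Mb only, and to 1.01 (-0.87 to 2.37) when interactions were counted in place of PETs. With every deposited pair, log2 ratios were lower at both 13q34 regions, 2.86 against 3.73 at 110436512 and 2.09 against 2.98 at 111364170. The ratio was also lower at 6p24.2, 2.80 against 3.19. It was higher at 6p22.3, 19q13.41 and 11q13.1.

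In 5 of the 6 LNCaP regions, the leading contact was with an anchor 2.64 to 4.13 kb away and carried most of the PETs. In each of these the leading partner was the next anchor along, as at 20q13.13, where it ended at 47896386 and the region began at 47897233. Whether these contacts, and their absence in other lines, follow from how peaks were divided was not analysed here. Region 47897233 to 47898450 of chromosome 20, at 20q13.13, had 31 PETs and a rate at least 14.3-fold higher than in the other lines, and 27 of its PETs led to an anchor 2.64 kb away. At 3p21.1, region 52721581 to 52723913 of chromosome 3 had 27 PETs (at least 12.5-fold), 22 of them to an anchor 2.73 kb away. Neither region had a deposited anchor in another line. On chromosome 17, regions at 17q25.3 (80224573 to 80228465, 25 PETs), 17p13.1 (7122319 to 7125120, 25 PETs) and 17q23.1 (57917247 to 57918770, 22 PETs) were also LNCaP-specific. At 17q25.3 the deposited PETs were 35 in LNCaP, 8 in VCaP, 3 in RWPE-1 and 1 in DU145. The 17p13.1 region had 4 PETs in RWPE-1 and a ratio of 11.4 (3.93 to 45.0), and its deposited PETs numbered 34 in LNCaP against 8 to 10 in the other lines. The 12q24.21 region, 115105566 to 115110701 on chromosome 12, had 21 PETs, 11 of them to an anchor 13.8 kb away, 7 to one at 4.71 kb and 3 to one at 245 kb. Its rate was at least 9.69-fold higher, and VCaP had 4 deposited PETs there. With PETs drawn down to the smallest library, its log2 ratio fell from 3.28 to 0.85 (-0.60 to 1.97). Counted by interactions, the log2 ratio of the 20q13.13 region fell from 3.84 to 1.48 (-1.56 to 3.33), and the intervals of all but the 17p13.1 region included 0. With every deposited pair, the log2 ratios of all 6 LNCaP regions were lower, as 3.12 against 3.84 at 20q13.13 and 1.38 against 3.51 at 17p13.1. LNCaP had 28 regions at least 2-fold above the highest other line, of 72 with at least 20 PETs.

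DU145 regions were led by a loop at 1q21.3. Regions 153505167 to 153509399 and 153537323 to 153541949 of chromosome 1 were joined over 32.5 kb by 46 PETs in DU145; RWPE-1 had 3 called PETs at each and the androgen receptor-positive lines had no called PET. Deposited PETs in RWPE-1 were 9 at the first and 13 at the second, where VCaP had 4 and LNCaP 2. Their rates were at least 12.8-fold and at least 11.8-fold higher than in the other lines. Counted by interactions, their log2 ratios fell from 3.67 to 1.104 (-1.17 to 2.65) and from 3.56 to 0.52 (-2.53 to 2.37), and the intervals of both 18p11.31 regions also included 0. At 18p11.31, regions 3593195 to 3596736 and 3602227 to 3605751 of chromosome 18 had 37 and 45 PETs, with ratios of 6.68 over LNCaP (2.40 to 25.8) and 6.57 over RWPE-1 (3.17 to 15.3). Both were joined to an anchor at 3621911 to 3625957, by 11 and 26 PETs. The 7q32.3 region, 130595267 to 130599102 on chromosome 7, had 28 PETs with 6 partners and a rate at least 6.74-fold higher, with 2 deposited PETs in RWPE-1. At 1q21.2, region 149856454 to 149860725 had 33 PETs and 9 partners, 7.94-fold above LNCaP (2.49 to 40.5), and partners as far as 1q44, 94156 kb away. Its deposited PETs were 94 in DU145, 57 in VCaP, 40 in LNCaP and 31 in RWPE-1. DU145 had 33 regions at least 2-fold above the highest other line, of 102 with at least 20 PETs, and all 33 had a deposited anchor in another line.

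RWPE-1 regions included a loop at 7q31.2 and clusters of contacts at 5q11.2 and 8q24.21. At 7q31.2, regions 116138595 to 116141604 and 116163946 to 116167501 of chromosome 7 were joined over 25.4 kb by 23 PETs. They had 27 and 28 PETs in total, with rates at least 4.95-fold and at least 5.13-fold higher than in the other lines; DU145 had 3 called PETs at the second and VCaP and LNCaP no deposited PET at either. Deposited PETs in DU145 were 4 at the first and 9 at the second. At 8q24.21, region 128490153 to 128495782 of chromosome 8 had 28 PETs with 5 partners, among them anchors 79.4 and 445 kb away, and no deposited PET in the cancer lines. The 5q11.2 region, 57754315 to 57756956 on chromosome 5, had 28 PETs with 7 partners, at distances of 271 to 621 kb for the leading 3; its deposited PETs were 57 in RWPE-1, 31 in VCaP, 3 in LNCaP and 4 in DU145. At 19p13.11, region 18388396 to 18389524 of chromosome 19 had 36 PETs (at least 6.60-fold), 31 of them to an anchor 2.77 kb away. That anchor was the next one along, beginning at 18389834, and the division of peaks was not analysed there. The 5q35.3 region, 176923084 to 176925544 on chromosome 5, had 28 PETs and a rate at least 5.13-fold higher, with 38 deposited PETs against 24 in VCaP, 8 in LNCaP and 7 in DU145. Counted by interactions in place of PETs, the log2 ratio was 0.036 (-3.01 to 1.89) at 19p13.11 and at both 7q31.2 regions. RWPE-1 had 44 regions at least 2-fold above the highest other line, of 122 with at least 20 PETs. The median anchor depth of line-specific regions that also had an anchor elsewhere was 1.46-fold (LNCaP) to 1.96-fold (DU145) that of the highest other line. The depth was at least 2-fold for 46 of 101 such regions in VCaP, 8 of 25 in LNCaP, 15 of 33 in DU145 and 12 of 37 in RWPE-1, so part of the differences may follow anchor depth. Among the 24 regions named above, 7 had no deposited anchor elsewhere, and the anchor depth of the other 17 was 1.46-fold to 27.3-fold that of the highest other line, with a median of 2.76-fold and 11 at 2-fold or more.

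**Figure D3:**
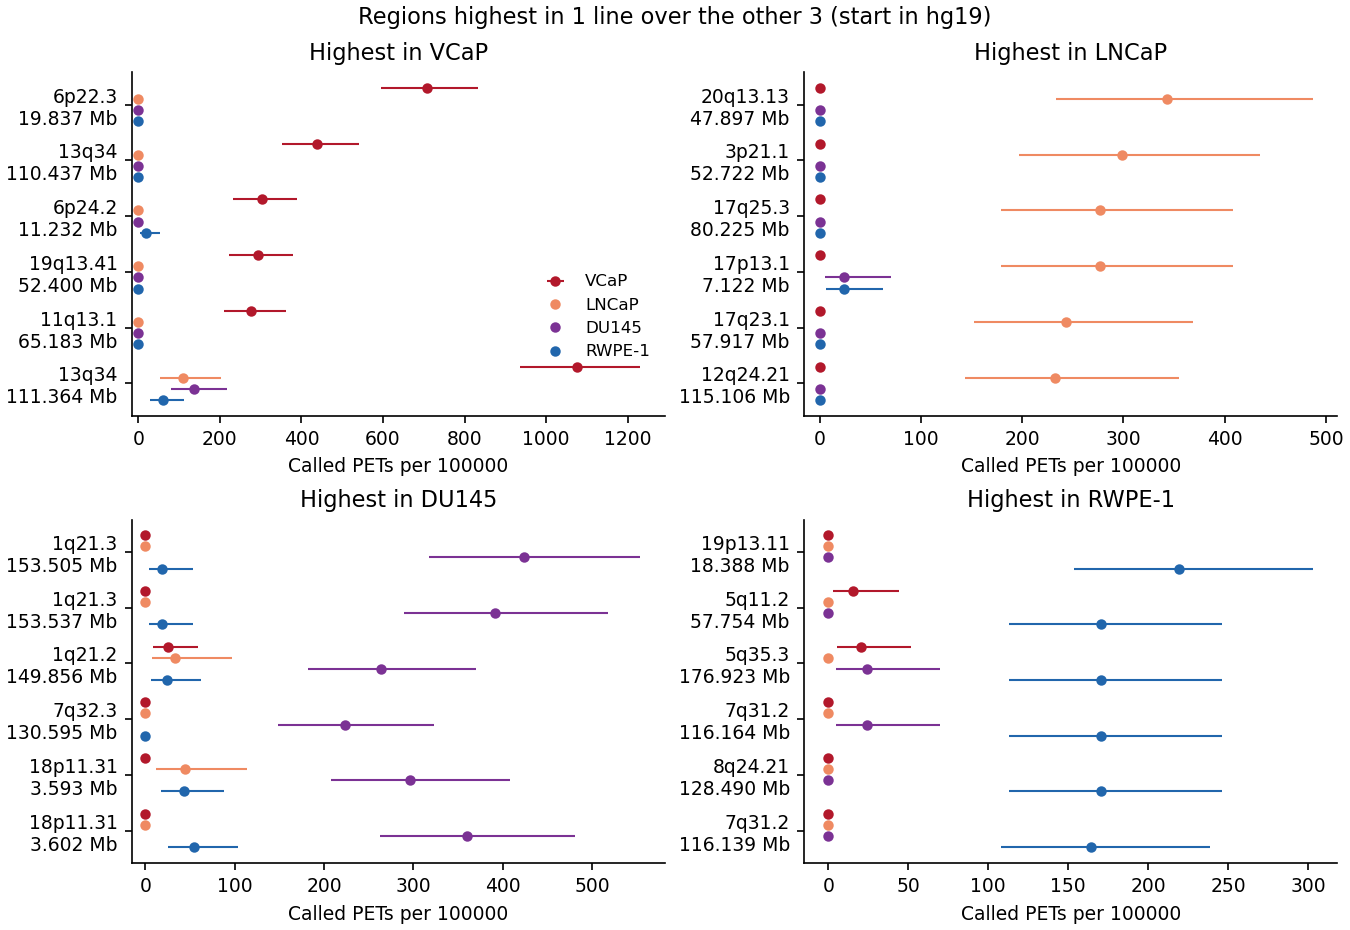
Called PETs per 100000 (horizontal axis) at the 6 regions of each line (vertical axis, band and start in hg19) with the highest ratio over the other 3 lines; points are rates per line and bars exact Poisson 95% intervals, not drawn for rates of 0. The 6p22.3 region reaches 707 PETs per 100000 in VCaP and 0 in the other lines.

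Regions called in the 3 cancer lines and not in RWPE-1 were few. There were 195 such regions, against 91 when VCaP was the line left out, 293 for LNCaP and 223 for DU145. These counts also depend on how many regions a line had, 3100 in LNCaP, 4217 in DU145, 5359 in VCaP and 5975 in RWPE-1. A line with fewer called regions can lack more of those found in the other lines. RWPE-1 had the most regions and yet lacked more than VCaP, so the counts do not rank how far a line stands apart. RWPE-1 had deposited PETs at 158 of the 195. With PETs drawn down to the smallest library there were 92. Without DU145, 715 regions were called in VCaP and LNCaP and not in RWPE-1. The leading region of the 195, at 11q13.1 (65185419 to 65188274 on chromosome 11), was picked by its rates after they were seen. It had 120 PETs in VCaP, 35 in LNCaP, 24 in DU145 and no deposited anchor in RWPE-1. It ends just before the 11q13.1 region at 65188319, which had 72 PETs in RWPE-1. A pair joining these neighbours carried 51 PETs in VCaP, 24 in LNCaP and 21 in DU145. Whether the absence in RWPE-1 follows from how peaks were divided was not analysed here. Regions called in RWPE-1 alone numbered 3812, or 63.8% of its regions, against 53.5% for VCaP, 45.2% for LNCaP and 49.5% for DU145. The narrower and less deep anchors of RWPE-1 were not separated from this share.

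Each cancer line had regions with higher and with lower interaction rates than RWPE-1. Among regions with at least 20 PETs in either line, 205 of 344 were at least 2-fold higher in VCaP and 74 at least 2-fold lower. Regions entered through either line, and those with at least 20 PETs numbered 268 in VCaP, 72 in LNCaP, 102 in DU145 and 122 in RWPE-1. The balance of higher and lower regions, and the median ratio, therefore depend in part on which line brought more regions in. In LNCaP, 54 of 167 were higher and 68 lower, and under the median-of-ratios scale 35 were higher and 89 lower. In DU145, 62 of 184 were higher and 66 lower, a balance that turned to 55 higher and 32 lower with PETs drawn down and to 191 and 111 with every deposited pair. The median log2 ratio to RWPE-1 was 1.71 for VCaP, -0.37 for LNCaP and 0.20 for DU145. The excess of higher regions in VCaP depended on its depth: with PETs drawn down to the smallest library, 30 regions were higher and 37 lower.

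The most connected regions were at 2p22.3, 13q34 and 11q13.1. The 2p22.3 region, 33140796 to 33142281 on chromosome 2, had 30 partners in VCaP, 8 in LNCaP, 8 in DU145 and 9 in RWPE-1, and all of its called interactions in each line spanned over 1 Mb. In VCaP the 13q34 region at 111364170 had 25 partners and the 11q13.1 region at 65188319 had 22, of which 20 lay outside the merged region. The hubs of LNCaP were 11q13.1 (65264403 to 65268986) and 2p22.3 with 8 partners each and, among 13 regions with 5 partners, 1p35.3 (28831600 to 28842412 on chromosome 1). That region had 3 partners outside itself and 9 of its 18 PETs inside, while 11 of the 13 had 5 partners outside. DU145 had 9 partners at each of its hubs, 11q13.1 at 65188319, 1q21.2 at 149856454 and 1p11.2 (121483890 to 121486006), the last beside the centromere. With partners outside the region only, 11q13.1 had 7, fewer than the 8 of 2p22.3. The 1p11.2 region had 211 deposited PETs in DU145, 149 in VCaP, 105 in LNCaP and 128 in RWPE-1. Its leading partners in DU145 lay 76642 to 94294 kb away. Reads placed at a repeated sequence were not examined there. RWPE-1 had 9 partners at 2p22.3 and 8 at each of 4 regions, 1q32.3 (212779622 to 212783965 on chromosome 1), 19p13.13 (13949402 to 13954514 on chromosome 19), 3q29 (193851241 to 193860507 on chromosome 3) and 5q35.1 (172191468 to 172199077 on chromosome 5). The 19p13.13 region also had 41 PETs in DU145 and no called PET in VCaP or LNCaP. Called anchors formed 1899 networks in VCaP, 1281 in LNCaP, 1643 in DU145 and 2375 in RWPE-1, of which 69.2% to 76.1% held a single pair. With PETs drawn down to the smallest library, the most connected VCaP region had 12 partners. The largest network, with 117 anchors and 200 interactions, lay on chromosome 11 in VCaP.

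Called interactions over 1 Mb were more common in DU145 and RWPE-1 than in VCaP and LNCaP, an order that did not hold for all deposited pairs. They numbered 465 in DU145 (17.2%, 15.8 to 18.7) and 419 in RWPE-1 (11.1%, 10.1 to 12.1). VCaP had 84 (2.18%, 1.75 to 2.70) and LNCaP 13 (0.671%, 0.358 to 1.14). With every deposited pair, the share over 1 Mb was 38.3% in VCaP, 23.2% in LNCaP, 40.4% in DU145 and 25.2% in RWPE-1, so that VCaP was above RWPE-1. Deposited pairs over 1 Mb with at least 2 PETs made up 16.1% of such pairs in DU145 and 21.6% in RWPE-1, against 2.93% in VCaP and 1.02% in LNCaP. With a minimum of 5 PETs the RWPE-1 share fell to 5.18%. In VCaP the leading pair of 1 Mb bins joined 6p24.2 (11092820 to 11480633) to 6p22.3 (19836679 to 19840036) by 130 PETs in 16 called interactions. The other lines had no deposited PET for this pair of bins and no deposited anchor at its 6p22.3 end. The second, on chromosome 21, joined 21q22.2 (39869117 to 39876858) to 21q22.3 (42853350 to 42864409) by 22 PETs in 3 called interactions. The deposited list held 37 PETs in 16 pairs there and the other lines none. VCaP is known to carry a fusion of TMPRSS2 and ERG, genes of 21q22; whether these anchors lie in those genes was not analysed here. The third joined 2p22.3 to 2q37.3 by 19 PETs, with deposited PETs in all 4 lines. In LNCaP the leading bins joined 17p13.1 (7215942 to 7220052) to 17q21.31 (41976637 to 41978408) by 8 PETs and 2p22.3 to 2q37.3 by 8, both with deposited PETs in all 4 lines. In DU145 the leading bins were 1q21.1 (144533039 to 144534995) and 1q21.2 (149222647 to 149225385), joined by 18 PETs, with 11 deposited PETs in RWPE-1, 4 in LNCaP and none in VCaP. The second in DU145, and the first in RWPE-1, joined 1p36.13 to 1q21.2 by 14 PETs in each; VCaP had 9 deposited PETs there and LNCaP 3. A pair on 21q22.12 (36541447 to 36542586) and 21q22.13 (38045142 to 38046281) had 13 PETs in DU145 and none in the other lines. The second in RWPE-1 joined 2p22.3 to 2q33.3 by 14 PETs, with deposited PETs in all 4 lines. The third, found in RWPE-1 alone, joined anchors of 20q13.12 (43964755 to 43977967 and 45034076 to 45318949) by 12 PETs.

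**Figure D4:**
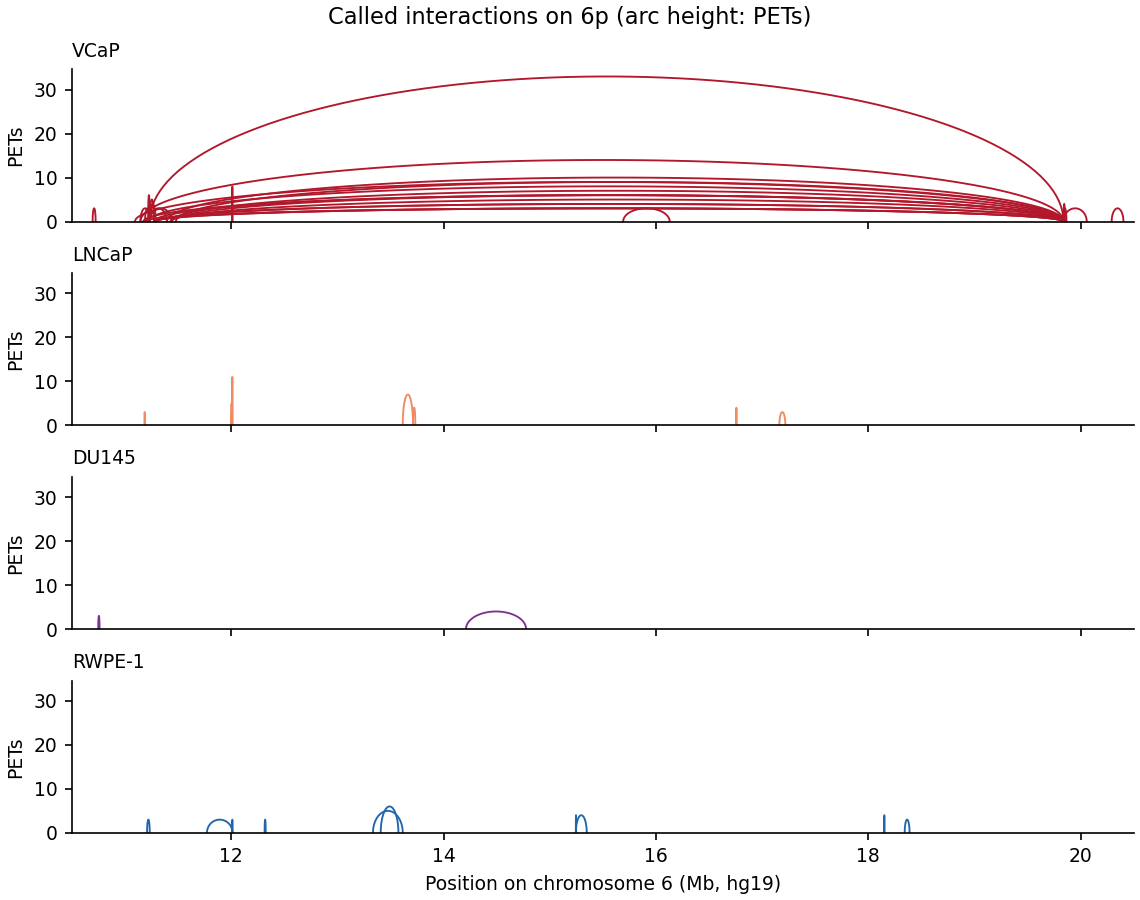
Called interactions on 6p in each line, drawn as arcs between anchor midpoints (horizontal axis, Mb on chromosome 6, hg19) with the number of PETs as arc height (vertical axis). In VCaP 16 of 30 interactions span over 1 Mb, all between 6p24.2 and 6p22.3; the other 3 lines have none over 1 Mb in this window.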

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

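Signals below the minimum of 3 PETs, which the called interactions leave out, stood out in 4 pairs of 1 Mb bins. In VCaP, 69 pairs with 1 or 2 PETs joined 63 to 64 Mb of chromosome 11 to 65 to 66 Mb of 11q13.1, against 0 in LNCaP, 1 in DU145 and 1 in RWPE-1. Between 65 to 66 Mb and 67 to 68 Mb (11q13.2), VCaP had 65 such pairs and the other lines 0 to 5. Between 64 to 65 Mb and 66 to 67 Mb, VCaP had 43 and the other lines 0 to 2. In DU145, 11 such pairs joined 14q13.2 (35 to 36 Mb of chromosome 14) to 14q21.3 (50 to 51 Mb), against 0 in VCaP, 1 in LNCaP and 0 in RWPE-1. These bin pairs were picked for standing above the other lines, so the difference is described and not tested.

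Of the tests below, those on 6p in VCaP and the test of distance at 2p22.3 were chosen after the result was seen; the others were written down before their values.

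For called interactions over 1 Mb in DU145 and RWPE-1, random pairing of the same PETs by anchor depth gave at most 5 called pairs in DU145 and 3 in RWPE-1, and the observed numbers were 93 and 140-fold higher than the highest of 100 simulations. The simulation draws PETs as independent molecules and does not cover a chance product that was counted several times, so the bound written for it was wrong and chance ligation stays open. Joined segments were predicted to place further pairs beside each interaction. Another deposited pair within 100 kb at both ends was found for 5.16% of the DU145 pairs (3.33 to 7.58) and 4.53% of the RWPE-1 pairs (2.75 to 6.99). Depth-matched pairs with a single PET gave 5.16% and 4.15%, so no excess of neighbours was seen for the set as a whole. In VCaP the same share was 51.2%, or 39.7% (28.0 to 52.3) without the 6p join described next, against 25.5%. In LNCaP it was 38.5% of 13 pairs (13.9 to 68.4), against 6.15%. By geometric mean of both anchor depths, the median of these called pairs was 5498 in VCaP, 3366 in LNCaP, 912 in DU145 and 527 in RWPE-1. Whether neighbours of joined segments would be seen at the lower depths was not tested, so these shares cannot decide on joined segments. Repeated counting of single ligation products, chance ones included, was predicted to give such shares and stays open. Joined segments and a difference between the lines in distant contacts also stay open.

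In VCaP the join of 6p24.2 to 6p22.3 carried 150 deposited PETs. Random pairing by depth gave at most 22 PETs in a bin pair of chromosome 6, 6.82-fold fewer, although it reached 84 elsewhere in the genome. The other 3 lines had none, with an upper limit of 1.62% of the VCaP rate. They held no deposited anchor at the 6p22.3 region, where all 16 called interactions of the join ended in VCaP. A line without a peak there could list no PET to it. Their lack of PETs therefore cannot decide on reads placed wrongly at sequence shared by both segments. The 150 PETs of VCaP were spread over 32 distinct anchor pairs, above those 22 even with each pair counted once. A candidate explanation is that the segments lie side by side in VCaP through a rearrangement; this was found and tested on the same library, and no genome sequence was analysed here.

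The 2p22.3 hub made interactions over 1 Mb in 100% of its called pairs in each of the 4 lines, against 0.259% to 17.0% of all others. Its depth accounts for little of this, since its PETs over 1 Mb were at least 10.5-fold those of random pairing by depth in every line, and at least 7.74-fold with each anchor pair counted once. A signal that ignores distance, as reads placed at a repeated sequence would give, may explain the hub and stays open; no sequence was used here to examine it. No biological explanation was tested, since the hub appears in all 4 lines.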

How the results depend on the processing

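A count was taken as moved when it changed by over 1.5 times and a share when it left the 95% interval of its main value. Of 32 results, every deposited pair moved 31, a minimum of 5 PETs 24 and PETs drawn down to the smallest library 21. VCaP lost its lead in calls and in line-specific regions (at least 20 PETs and 2-fold above the highest other line) when PETs were drawn down, and the rank of VCaP and LNCaP in shared interactions changed. The 24 named line-specific regions had log2 ratios of 0.036 to 5.00 under the alternatives that gave them a value; 4 had no interaction of 10 kb to 1 Mb. Intervals of these ratios, which cover the counting error of the line itself, included 0 for 15 regions by number of interactions, the lowest at 19p13.11 and both 7q31.2 regions with 0.036 (-3.01 to 1.89). They included 0 also for 6p22.3 with interactions of 10 kb to 1 Mb only, 0.38 (-0.68 to 1.26), for 12q24.21 with PETs drawn down, 0.85 (-0.60 to 1.97), and for 5q11.2 with a minimum of 5 PETs, 1.046 (-0.014 to 1.92). Overlap of at least 50% of the shorter anchor, a limit of 2 Mb, the removal of mitochondrial pairs and that of contacts inside a region, the last 2 chosen after seeing the data, moved no result listed here. No point estimate of a named region fell below 0. The cause was not tested except where the alternative's construction gives it, as fewer pairs at a higher minimum. Alternatives on false discovery rates, promoter windows, gene lists and their pseudocount were not run. No paired analysis was possible because each line had 1 library.

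With every deposited pair, interactions numbered 66187 in VCaP, 39071 in LNCaP, 24578 in DU145 and 28465 in RWPE-1. The percentage of interactions shared with any other line was 13.7 in VCaP, 19.6 in LNCaP and 22.27 in DU145. For anchors it was 58.5 in VCaP, 60.9 in LNCaP, 69.3 in DU145 and 51.1 in RWPE-1. The percentage over 1 Mb was 38.3 in VCaP, 23.2 in LNCaP, 40.4 in DU145 and 25.2 in RWPE-1. Regions at least 2-fold above RWPE-1 numbered 753 in VCaP, 137 in LNCaP and 191 in DU145, and those below it 158, 171 and 111. The most partners of a region were 243 in VCaP, 117 in LNCaP, 167 in DU145 and 174 in RWPE-1. Regions in all 3 cancer lines and not RWPE-1 numbered 2374, and those in RWPE-1 alone 15299. Line-specific regions numbered 319 in VCaP, 51 in LNCaP, 120 in DU145 and 86 in RWPE-1.

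With a minimum of 5 PETs, calls numbered 1273 in VCaP, 525 in LNCaP, 831 in DU145 and 966 in RWPE-1. Interactions were shared with any other line for 46.1% in LNCaP, 28.6% in DU145 and 21.6% in RWPE-1. Anchors were shared for 37.9% in VCaP, 40.9% in DU145 and 31.8% in RWPE-1. Interactions over 1 Mb made up 11.9% in DU145 and 5.18% in RWPE-1. Regions above RWPE-1 numbered 133 in VCaP, 27 in LNCaP and 38 in DU145, and those below it 46, 40 and 38. The most partners were 14 in VCaP, 4 in LNCaP, 7 in DU145 and 6 in RWPE-1. Regions in all 3 cancer lines and not RWPE-1 numbered 73, and those in RWPE-1 alone 1160. Line-specific regions numbered 78 in VCaP, 17 in LNCaP, 25 in DU145 and 27 in RWPE-1.

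With PETs drawn down to the smallest library, calls numbered 1128 in VCaP, 1279 in LNCaP and 2769 in RWPE-1. Interactions were shared for 34.7% in VCaP, 31.1% in LNCaP, 18.8% in DU145 and 16.0% in RWPE-1. Anchors were shared for 55.6% in VCaP, 46.8% in LNCaP, 38.7% in DU145 and 32.5% in RWPE-1. Regions above RWPE-1 numbered 30 in VCaP and 25 in LNCaP, and those below it 37 in VCaP, 35 in LNCaP and 32 in DU145. The most partners were 12 in VCaP and 5 in LNCaP, and 92 regions were in all 3 cancer lines and not RWPE-1. Line-specific regions numbered 25 in VCaP, 14 in LNCaP, 31 in DU145 and 16 in RWPE-1.

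With a limit of 500 kb, long-range interactions made up 2.99% in VCaP, 1.19% in LNCaP, 19.2% in DU145 and 12.5% in RWPE-1. With anchors within 5 kb counted as shared, interactions were shared for 34.7% in VCaP, 45.6% in LNCaP, 31.4% in DU145 and 24.1% in RWPE-1, and anchors for 53.7%, 62.3%, 55.9% and 42.5%. Under the median-of-ratios scale, 35 regions were above RWPE-1 and 89 below it in LNCaP, and 17 were LNCaP-specific. With interactions of 10 kb to 1 Mb only, regions above RWPE-1 numbered 98 in VCaP, 19 in LNCaP and 22 in DU145, and those below it 28, 25 and 27, while line-specific regions numbered 57 in VCaP, 10 in LNCaP, 13 in DU145 and 18 in RWPE-1. In the same window, chosen after seeing the data for these results, interactions were shared for 24.3% in VCaP and anchors for 42.5% in VCaP and 46.4% in DU145. It left 111 regions in all 3 cancer lines and not RWPE-1, and 2212 in RWPE-1 alone. With an equal number of pairs per line, also chosen after seeing the data, interactions were shared for 34.8% in VCaP, 31.3% in LNCaP, 23.5% in DU145 and 21.5% in RWPE-1, and anchors for 51.5%, 45.0% and 42.2% in the cancer lines. Without DU145, chosen after seeing the data, 715 regions were in VCaP and LNCaP and not RWPE-1.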

Other observations

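Anchor depth along the genome set each line apart at a few places, and several of these were also places of line-specific interactions. At regions with a deposited anchor in all 4 lines, VCaP depth exceeded the median of the other lines most at 63 to 64 Mb of 11q13.1, with a median log2 difference of 1.71 over 9 regions. The adjacent bins from 64 to 67 Mb had values of 1.14, 1.18 and 1.11 over 25, 36 and 21 regions. VCaP also exceeded the others over 21q as a whole, by 0.84 over 63 regions. The 1 Mb bins of highest DU145 depth were on chromosome 14, at 50 to 51 Mb (14q21.3, 1.61 over 16 regions) and 35 to 36 Mb (14q13.2, 1.38 over 12 regions), the same bins that low-count pairs joined in this line. By arm, DU145 had 0.69 over the 23 regions of 18p, which holds a pair of its line-specific regions, 0.64 over the 50 regions of 5p and 0.45 over 14q. The 1 Mb bin of highest RWPE-1 depth was on 20q, with 1.39 at 48 to 49 Mb (20q13.13, 10 regions) and 0.84 over the 164 regions of the arm. The 1 Mb bin of highest LNCaP depth was at 46 to 47 Mb of 22q13.31, with 1.19 over 5 regions and no named LNCaP region, followed by 52 to 53 Mb of 3p21.1 with 1.01 over 11 regions, the band of a LNCaP-specific region. Over the 114 regions of 3p, LNCaP and VCaP were close, at 0.61 and 0.57, with DU145 at -0.43 and RWPE-1 at -0.87.

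Within each line, the PETs of deposited pairs of 10 kb to 1 Mb rose with the depth of their anchors and fell with distance. Spearman's rho across pairs with depth was 0.30 in VCaP, 0.27 in LNCaP, 0.21 in DU145 and 0.24 in RWPE-1. With distance it was -0.20 in VCaP, -0.18 in LNCaP, -0.13 in DU145 and -0.081 in RWPE-1. Pairs that share an anchor are not independent, so no p is given.

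The largest network of VCaP ran from 11p15.3 to 11q22.3 with 1761 PETs, and chromosome 11 held 13.8% of the called PETs of VCaP against 5.00% in RWPE-1 to 7.35% in LNCaP. A network of 34 anchors within 0.769 Mb of 13q34 carried 313 PETs in VCaP.

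Pairs over 1 Mb reached 3 PETs at different rates in the 4 lines. Had pairs within 1 Mb reached 3 PETs at that rate, they would have given 135 calls in VCaP (3.60% of its calls within 1 Mb), 43.1 in LNCaP (2.24%), 685 in DU145 (30.6%) and 1243 in RWPE-1 (37.0%).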
